A study of Mus musculus with 14 samples.

How the data were processed

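Nuclei from heart tissue of male C57BL/6J mice, 12 weeks old, were sonicated and histone and DNA complexes were precipitated with an antibody against H3K9ac or H3K9Bu, per the labels. The labels give a pool of 3 per precipitation. There were 12 ChIP libraries, 1 for each mark, surgery (sham or TAC) and diet (0, 10 or 60% of energy from fat). Another 2 libraries hold pooled input DNA; no column could be tied to them, and they were not used here. Each group has 1 library, so no test between single groups was made and no replicate could be left out; fits that pool the diets were not made.

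Reads were aligned with BWA to mm10 and regions called with SICER, per the submitters' processing notes; versions, tag filtering, use of the inputs and scaling between libraries are not stated in the sources used here. The authors merged the called intervals of 4 libraries into common regions in each of 3 tables: both marks at 0% fat (49314 regions), H3K9ac at 10 and 60% fat (38150 regions) and H3K9Bu at 10 and 60% fat (58137 regions). The deposited average and peak values are a signal, the mean and the maximum tag density over the merged region, per the file headers. Levels were compared only within a table. The authors also give a log2 ratio of average signals for pairs of libraries; 483770 of 483770 deposited log2 values were equal to ratios recomputed from the averages within 1e-06, and 6 cells held an error instead of a value. Other deposited columns, per the file headers, are an estimated tag number, a mark of 0 or 1 for presence in each library, and the coordinates, lengths and annotation counts of each region.

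The deposited estimated tag number equals the larger of the compared average signals times the region's length divided by 224 in 483776 of 483776 cells. That relation was used to estimate tags per library and region. Depth is known only as these estimated tags within the merged regions, from 2543841 to 9163220 per library, since total reads are not in the tables. Exact (Clopper-Pearson) intervals at 95% for the share of the tags of both libraries that fell in one of them, turned into ratios, give the precision of single genes and cover counting error only. Tags are not known to be independent molecules.

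A promoter was the window from 7500 bp upstream to 2500 bp downstream of the gene start, which gives the file's own promoter count in 125359 of 125367 regions. Each gene was assigned the overlapping region with the highest mean signal over the table's 4 libraries, and regions under the table's 25th percentile of mean signal were left out. This left 13666, 14007 and 12046 genes in the 3 tables, in the order above. The log2 ratio was taken on the signal as deposited plus a pseudocount of 1. Genes past 1.5-fold and 2-fold were counted, with the split after centring on the median over genes and after a lowess trend on mean log2 signal (fraction 0.3). Of 17063 gene symbols in the tables, 15392 matched a symbol and 16532 a symbol or synonym of the RefSeq annotation of GRCm38, from which gene IDs were taken. Several genes may share a region, and such genes are not independent values.

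Before the data were examined, 34 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. A list with at least 4 measured members was compared, by its median log2 ratio, with 10000 random lists of as many genes from the same deciles of mean signal, and called apart in the lowest or highest 2.5%. With 348 such calls made, some lie outside these limits by chance: of 200 lists of unchanged genes drawn from each simulated comparison, 1.5 to 7.5% did. Named genes were the 10 highest and the 10 lowest ratios among promoters on autosomes or X whose larger signal reaches the table's median over genes, leaving out predicted, clone-named and small RNA symbols. To these come 3 members of each list called apart, those farthest in its direction, and a fixed set of heart and metabolism genes (among them Nppa, Nppb, Myh7, Acta1, Myh6, Pdk4, Acot1, Cpt1b, Acads, Scd1, Col1a1, Postn, Per2, Gapdh) where measured. Some genes under this rule are not printed in the text. Nppa was under the filter at 0% fat, and neither Nppa in the other tables nor Acta1 had a promoter region. Postn, Col1a1, Myh7 and Nppb were not measured in the H3K9Bu table at 10 and 60% fat, and Postn was under the filter in the H3K9ac table at these diets.

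Alternatives were centring, lowess, peak in place of average signal, a pseudocount of 5, no filter, regions called in both libraries only, and the mean over all regions assigned to the gene. For overlaps they were a reciprocal 50% and regions at or above the table's median signal. Promoter regions with their centre within 2000 bp of the gene start and random lists matched also on whether the promoter region holds a CpG island were alternatives chosen after seeing the data. Overlap between marks was at least 1 bp, found with bedtools; at 0% fat it is presence of both marks in an authors' merged region, where a reciprocal overlap cannot be computed. Correlations across genes were taken for 13 pairs of comparisons that share no library. Shared genes were counted among genes at least 1.5-fold apart from the median in both comparisons and set beside the count that independent ratios would give.

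The procedure was tested on simulated data. For each comparison, tags of both libraries were drawn from the mean of their signals, and 200 regions were changed by 1.5, 2 or 3-fold. Both simulated libraries thus had the same expected depth. The numbers for counting error given with each comparison leave out unequal depth between its libraries. Of the 2-fold changes 91.67 to 100% passed the 1.5-fold limit, of the 3-fold changes 100%, and of the 1.5-fold changes 36.36 to 50%. Between 51 and 382 unchanged genes per comparison passed it by counting error. The list with added changes stood at percentile 100 in each comparison. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and bedtools 2.31.1.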

Results

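Hearts of male C57BL/6J mice were profiled by chromatin immunoprecipitation sequencing (ChIP-seq) for 2 acyl modifications of the same residue, lysine 9 of histone H3: acetylation (H3K9ac), which marks active promoters, and butyrylation (H3K9Bu), which carries a longer acyl chain. Mice were 12 weeks old. They ate a diet with 0, 10 or 60% of its energy as fat for 4 days before surgery and 1 week after it. Surgery was a sham operation or transverse aortic constriction (TAC), a narrowing of the aorta that loads the left ventricle with pressure. Each diet, surgery and mark is represented by 1 library made from a pool of 3, so 12 libraries were compared and the differences below have no replicate check. The series asks how dietary fat goes with both marks in the heart, with and without TAC.

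The authors' caller marked between 14679 regions (H3K9Bu, TAC, 60% fat) and 41348 regions (H3K9Bu, sham, 10% fat). The total number of reads per library is unknown. Tags estimated from the signal of each table's merged regions came to between 2543841 and 9163220 per library. The H3K9ac libraries held between 7936243 and 9163220. The H3K9Bu libraries at 10 and 60% fat held between 2543841 and 5194261. Among those 4 libraries, the sham 10% fat library stood apart: 21352 of its regions were called in that library alone, and its median promoter signal was 46.7 tags per position, against 22.7, 23.7 and 17.2 in the sham 60%, TAC 10% and TAC 60% fat libraries.

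**Figure D1:**
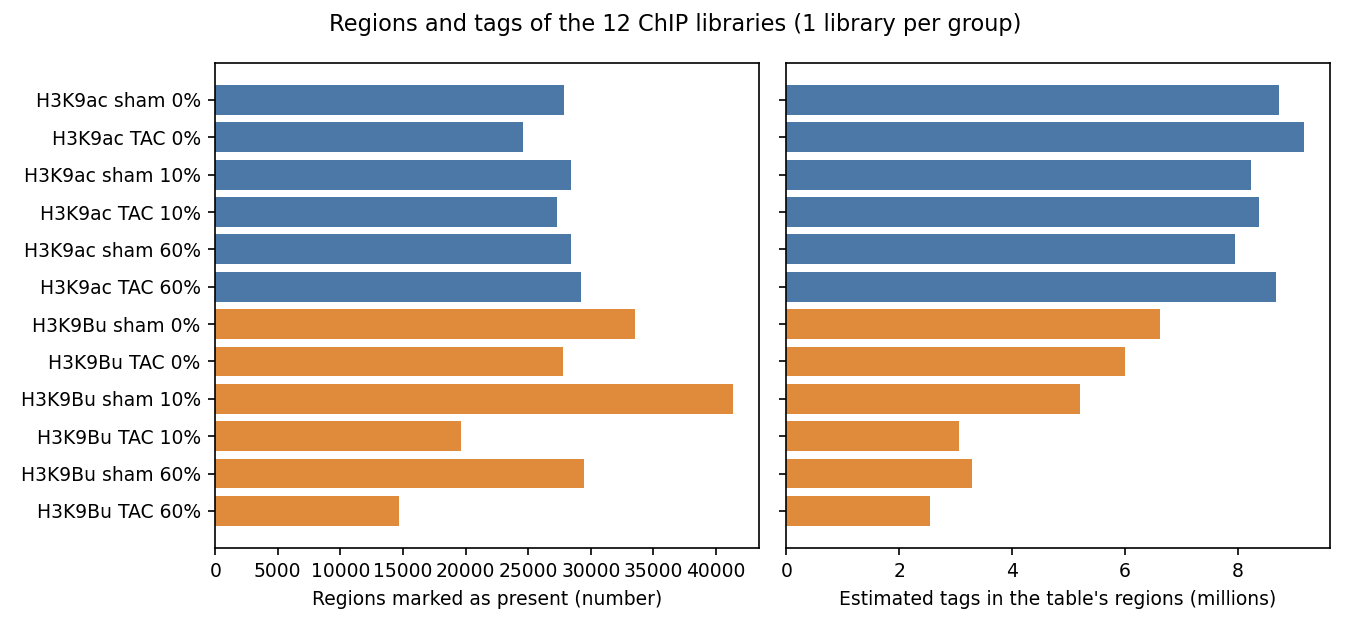
Regions marked as present by the authors' caller (left, number) and tags estimated in the merged regions of the library's table (right) for each of the 12 ChIP libraries, with 1 bar per library, H3K9ac in blue and H3K9Bu in orange. The H3K9Bu libraries at 10 and 60% fat hold fewer estimated tags (2543841 to 5194261) than the H3K9ac libraries (7936243 to 9163220).

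Signal is the authors' average tag density over a merged region (mm10), and each gene is represented by the strongest region overlapping its promoter. Ratios are log2 values with a pseudocount of 1. They are printed relative to the median ratio over all promoters of the same comparison, with a 95% counting interval in parentheses; the intervals cover counting error only. A gene list has a percentile among 10000 random lists of the same size and signal level; lists in the lowest or highest 2.5% are called below or above the other promoters, and these percentiles describe these libraries only. Promoters are ranked among those whose signal reaches the table's median over genes in either library.

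**Figure D2:**
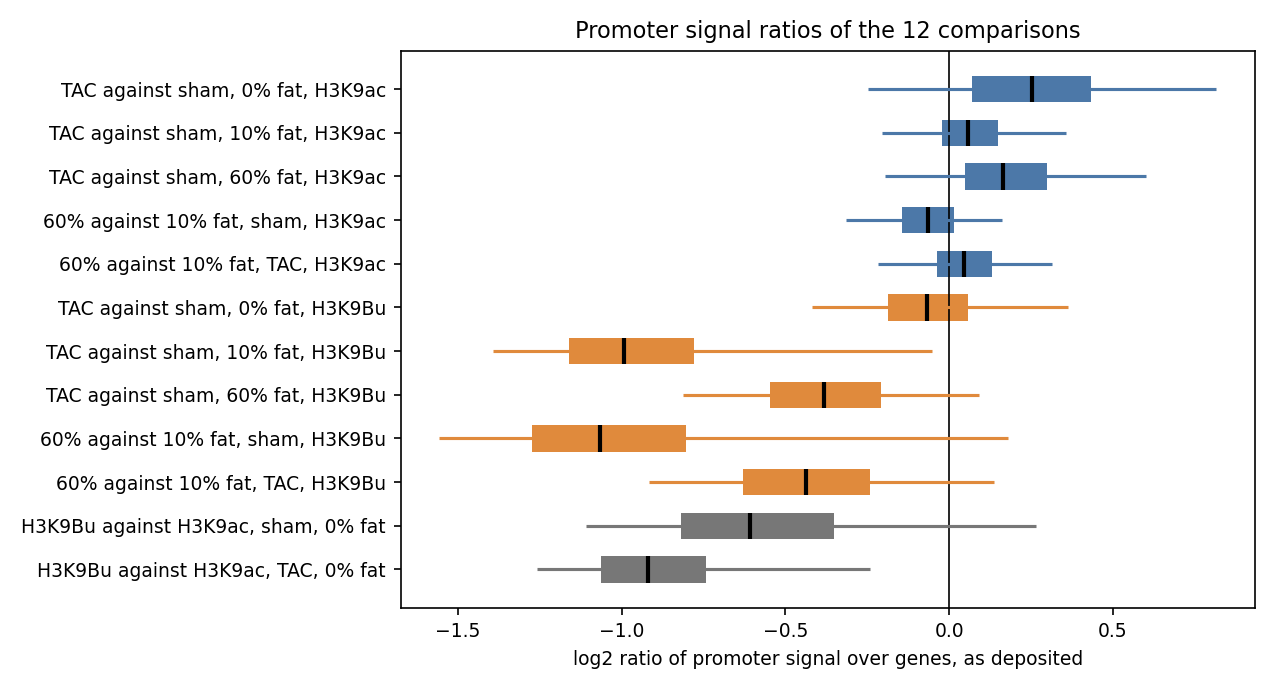
Distribution over genes of the log2 ratio of promoter signal, as deposited, for the 12 comparisons (H3K9ac blue, H3K9Bu orange, H3K9Bu against H3K9ac grey); boxes span the middle 50% of genes, lines run from the lowest 5 to the highest 5%, and black ticks are medians. The medians range from -1.07 to 0.25, and the H3K9Bu comparisons that use the sham 10% fat library have medians near -1.

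The response of promoter H3K9ac to TAC was compared at each diet. At 0% fat, the natriuretic peptide gene Nppb, a marker of ventricular load, carried more H3K9ac in the TAC library, with a relative log2 ratio of 1.53 (1.22 to 2.01) and signals of 50.2 against 13.9 (gene ID 18158, chromosome 4, 147985886 to 147987020). Macrophage and myeloid marker promoters were higher as a group (median 0.79, percentile 100), with 9 of 10 members above 0. Examples were Tyrobp, a signalling adaptor of myeloid cells, at 1.42 (1.07 to 1.95), and Csf1r, the receptor for macrophage colony-stimulating factor, at 1.04 (0.80 to 1.34). Fcgr1, a receptor for antibodies, stood at 1.10 (0.71 to 1.69) in a region centred at -6866 bp from the gene start. The highest of the ranked promoters was that of Pik3ap1, a signalling adaptor of immune cells, at 1.63 (1.16 to 2.28), and the interleukin receptor gene Il10ra stood at 1.25 (1.05 to 1.57).

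Promoters of extracellular matrix and fibrosis genes were also higher after TAC at 0% fat (median 0.28, percentile 99.76; 17 of 23 above 0). Thbs1, a matrix glycoprotein, stood at 1.10 (0.58 to 1.74), fibronectin Fn1 at 0.96 (0.72 to 1.29) in a region that also holds the Apol7d promoter, and the collagen crosslinking enzyme gene Lox at 0.86 (0.57 to 1.22). Tmem119 stood at 1.12 (0.67 to 1.69). Cell cycle promoters were above 0 in 14 of 19 members (median 0.40, percentile 100, a call that ended with peak signal), among them the proliferation marker Mki67 at 1.13 (0.83 to 1.504), the cyclin gene Ccnb2 at 1.36 (0.61 to 2.29) and the replication licensing gene Mcm6 at 0.85 (0.54 to 1.20).

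Several lists had less H3K9ac at 0% fat after TAC relative to the other promoters, and most of them had medians near 0 as deposited. PPAR target and lipid handling genes were among the lowest groups (median -0.37, percentile 0; as deposited -0.11; 18 of 19 below 0): the mitochondrial uncoupling protein gene Ucp3 stood at -1.15 (-1.35 to -0.98) (chromosome 7, 100472460 to 100474533), the lipase inhibitor gene Angptl4 at -0.75 (-0.88 to -0.64) and the fatty acid transporter gene Cd36 at -0.71 (-0.82 to -0.62). Oxidative phosphorylation genes were below 0 in 20 of 20 members (median -0.30, percentile 0; as deposited -0.05), and 0 of them were 1.5-fold lower, with Ndufb8 at -0.51 and Cyc1 at -0.50, in regions shared with other promoters. Sarcomere genes (median -0.28, percentile 0.02; as deposited -0.03) included Actc1, cardiac actin, at -0.46 (-0.59 to -0.33), ventricular cardiomyocyte markers had a median of -0.31, percentile 0.07 (as deposited -0.05), and adipocyte markers had a median of -0.39, percentile 0.04, a call that ended with peak signal (as deposited -0.14). Endothelial markers (median -0.28, percentile 0.23, as deposited -0.03) included Pecam1 at -0.48 and Egfl7 at -0.51. The Egfl7 region is centred at -9099 bp from the gene start. Ribosomal protein genes (median -0.29, percentile 0; as deposited -0.03) included Rpl18 at -0.67, in a region shared with other genes.

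Single regulators were low as well at 0% fat: the cardiac transcription factor gene Nkx2-5 stood at -0.81 (-1.003 to -0.65), Klf15, a glucocorticoid-induced regulator of metabolism, at -0.84 (-0.94 to -0.76), the potassium channel gene Kcnh2 at -0.66 (-0.92 to -0.40) and the metalloproteinase inhibitor gene Timp4 at -1.14 (-1.29 to -1.02). The lists around them were below the other promoters too: calcium handling and ion channels (median -0.19, percentile 1.01; as deposited 0.06), glucocorticoid and fasting response (median -0.15, percentile 0.635; as deposited 0.11) and cardiac transcription factors (median -0.20, percentile 0.39, a call that ended with peak signal; as deposited 0.05). Fatty acid oxidation genes had a median of -0.17, percentile 0.16, a call that ended with peak signal, with 0.08 as deposited, so their direction depends on the shift. The same holds for the TCA cycle (median -0.24, percentile 0.03, a call that ended with peak signal; as deposited 0.01). The cardiac myosin gene Myh6 stood at -0.34 (-0.41 to -0.27). Myh7, the fetal myosin, had an interval that includes 0, 0.26 (-0.35 to 0.98). The glycolytic control gene Gapdh stood at -0.13 relative and 0.12 as deposited.

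Of 13666 genes at 0% fat, the TAC library had 1842 promoters at least 1.5-fold higher and 121 lower as deposited, around a median ratio of 0.25; 325 were 2-fold higher and 15 2-fold lower. The split was 630 higher and 467 lower after centring on the median, and 355 higher and 603 lower after lowess centring. On peak signal, not centred, it was 3399 higher and 61 lower. Lists were 3 above and 12 below of 29. In simulated libraries that differ by counting error alone, 88 unchanged genes passed 1.5-fold. The sham 0% fat H3K9ac library had a lower ratio of peak to average signal in long regions, 1.94 against 2.25 to 2.37 in the other H3K9ac libraries, and 7007 regions were called in that library alone.

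At 10% fat, differences in H3K9ac between TAC and sham were smaller, and Nppb again stood high at 1.15 (0.82 to 1.57). Cell cycle promoters were above 0 in 16 of 19 members (median 0.19, percentile 99.97), with Mki67 at 0.85 (0.57 to 1.21), the mitotic kinase gene Cdk1 at 0.54 (0.31 to 0.84) and the cyclin gene Ccna2 at 0.50 (0.26 to 0.78). Cks2, a cofactor of cyclin-dependent kinases, and the nuclear lamina gene Lmnb1 stood at 0.40 and 0.37, and Arl4c, a small GTPase gene, at 0.53 (0.41 to 0.68). Immediate early genes had a median of 0.04, percentile 99.15, a call that ended with peak signal. Matrix and macrophage lists were not apart from random lists (extracellular matrix median 0.05, percentile 80.18; macrophage median -0.07, percentile 10.15), with Col1a1, a fibrillar collagen, at 0.15 (-0.07 to 0.39) and Tyrobp at -0.10 (-0.42 to 0.21).

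The lists below the other promoters after TAC at 10% fat had few members past 1.5-fold. PPAR target genes were below 0 in 16 of 19 members (median -0.23, percentile 0): Ucp3 stood at -0.65 (-0.80 to -0.52) and Pdk4, the kinase that restrains glucose oxidation, at -0.58 (-0.67 to -0.51). Glucocorticoid and fasting response genes were below 0 in 17 of 18 (median -0.30, percentile 0), with the muscle ubiquitin ligase gene Trim63 at -0.59 (-0.71 to -0.48) and Klf15 at -0.43 (-0.54 to -0.34). Sarcomere genes (median -0.22, percentile 0; Tcap, a titin-binding protein, -0.36, in a region shared with Pnmt), ventricular markers (median -0.24, percentile 0; phospholamban Pln -0.40) and cardiac transcription factors (median -0.19, percentile 0; Tbx5 -0.41) were low. The mitophagy receptor gene Bnip3 stood at -0.54 (-0.65 to -0.45). Ketone and branched-chain amino acid genes were below 0 in 14 of 14 (median -0.10, percentile 0.23; as deposited -0.04). Calcium handling genes (median -0.10, percentile 0.45, a call that ended with peak signal) included Kcnip2, a potassium channel subunit, at -0.70 (-0.93 to -0.51), and clock genes (median -0.10, percentile 0.16, a call that ended with peak signal; as deposited -0.04) were low as well. Lymphocyte markers had a median of -0.34, percentile 2.4, a call that ended with a pseudocount of 5 and with lists matched on CpG island. Myh6 stood at -0.26, while Acot1, a thioesterase gene, was higher at 0.41 (0.11 to 0.74).

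Of 14007 genes at 10% fat, 147 promoters were at least 1.5-fold higher and 53 lower, around a median of 0.06; 13 and 4 were 2-fold higher and lower. The split was 109 higher and 79 lower after centring on the median, and 56 higher and 120 lower after lowess centring, so its direction depends on the scaling. Counting error alone gave 51 genes past 1.5-fold in the simulation. Lists were 2 above and 9 below of 31.

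At 60% fat, cell cycle promoters were the highest group after TAC (median 0.43, percentile 100), with 17 of 19 members above 0 and 6 at least 1.5-fold higher. Mki67 stood at 1.58 (1.35 to 1.92), Cdk1 at 1.34 (1.14 to 1.64) and Ccnb2 at 1.01 (0.66 to 1.44). Uhrf1, which maintains DNA methylation at replication, stood at 1.01 (0.82 to 1.26) in a region shared with Arrdc5, and the mitotic motor gene Kif11 at 0.76 (0.61 to 0.96). Nppb stood at 1.37 (1.05 to 1.86). Matrix genes (median 0.22, percentile 99.92; 17 of 22 above 0) included Fn1 at 0.69 (0.45 to 0.99) and Col1a1 at 0.57 (0.37 to 0.80), and macrophage markers (median 0.34, percentile 99.74; 12 of 14 above 0) included Tyrobp at 0.87 (0.55 to 1.28) and the leukocyte phosphatase gene Ptprc at 0.71 (0.34 to 1.17). The sham 60% fat library was itself low against the sham 10% fat library at macrophage markers (median -0.39) and at Kif11 (-0.66). Macrophage markers were not apart between 60 and 10% fat after TAC (percentile 59.67). Nor were macrophage markers apart between TAC and sham at 10% fat, so at these markers the sham 60% fat library was the one that stood apart. The macrophage ratios of TAC to sham at 60% fat thus rest largely on that library. For Kif11, whether the sham 60% fat library was low or the sham 10% fat library high was not tested. Fibroblast markers had a median of 0.24, percentile 97.77, a call that ended with a pseudocount of 5 and with lowess centring and with peak signal. Emp1, a membrane protein gene, stood at 0.84 (0.71 to 1.01).

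The sarcomere, ventricular and PPAR lists were the lowest at 60% fat. Sarcomere promoters were below 0 in 18 of 20 members (median -0.41, percentile 0): Actc1 stood at -0.74 (-0.89 to -0.61), Tcap at -0.71 (-0.82 to -0.60) and the troponin gene Tnni3 at -0.68 (-0.83 to -0.55), the latter in a region shared with Tnnt1. Ventricular markers were below 0 in 14 of 14 (median -0.38, percentile 0), with Pln at -0.59 (-0.67 to -0.52), and atrial markers had a median of -0.22, percentile 1.95. PPAR target genes (median -0.36, percentile 0; 7 of 19 at least 1.5-fold lower) included Ucp3 at -0.82 (-0.96 to -0.70) and Plin5, a lipid droplet coat protein, at -0.82 (-0.97 to -0.69) in a region shared with Lrg1. Pdk4 stood at -0.64 (-0.73 to -0.57). Calcium handling genes (median -0.27, percentile 0) included Kcnip2 at -1.18 (-1.47 to -0.98) and Kcnh2 at -0.75 (-1.004 to -0.51). Cardiac transcription factors were below 0 in 19 of 20 (median -0.31, percentile 0), with the nuclear receptor gene Esrrb at -0.91 (-1.26 to -0.59).

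Glucocorticoid and fasting response genes were below 0 in 18 of 18 members at 60% fat (median -0.28, percentile 0), with Ddit4, an inhibitor of mTOR signalling, at -0.91 (-1.18 to -0.70), Trim63 at -0.76 (-0.90 to -0.64) and Klf15 at -0.64 (-0.76 to -0.54). Oxidative phosphorylation genes (median -0.18, percentile 0; as deposited -0.01) included Cox8b at -0.74 and Cox6a2 at -0.65, and autophagy genes (median -0.13, percentile 0.2, a call that ended with peak signal; as deposited 0.04) included Bnip3 at -0.82 (-0.94 to -0.72). Ketone and branched-chain amino acid genes had a median of -0.18, percentile 0.04, with -0.01 as deposited. Other low lists were fatty acid oxidation (median -0.16, percentile 0.01, a call that ended with peak signal; as deposited 0.01), the TCA cycle (median -0.13, percentile 0.15, a call that ended with peak signal; as deposited 0.03), ribosomal proteins (median -0.09, percentile 2.375, a call that ended with lowess centring; as deposited 0.07) and adipocyte markers (median -0.18, percentile 1.4, a call that ended with peak signal). Myh6 stood at -0.38 and Gapdh at 0.15.

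Of 14007 genes at 60% fat, 780 promoters were at least 1.5-fold higher and 92 lower, around a median of 0.17; 109 and 17 were 2-fold higher and lower. The split was 339 higher and 206 lower after centring on the median, and 269 higher and 256 lower after lowess centring. Lists were 4 above and 14 below of 31, and counting error alone gave 68 genes.

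**Figure D3:**
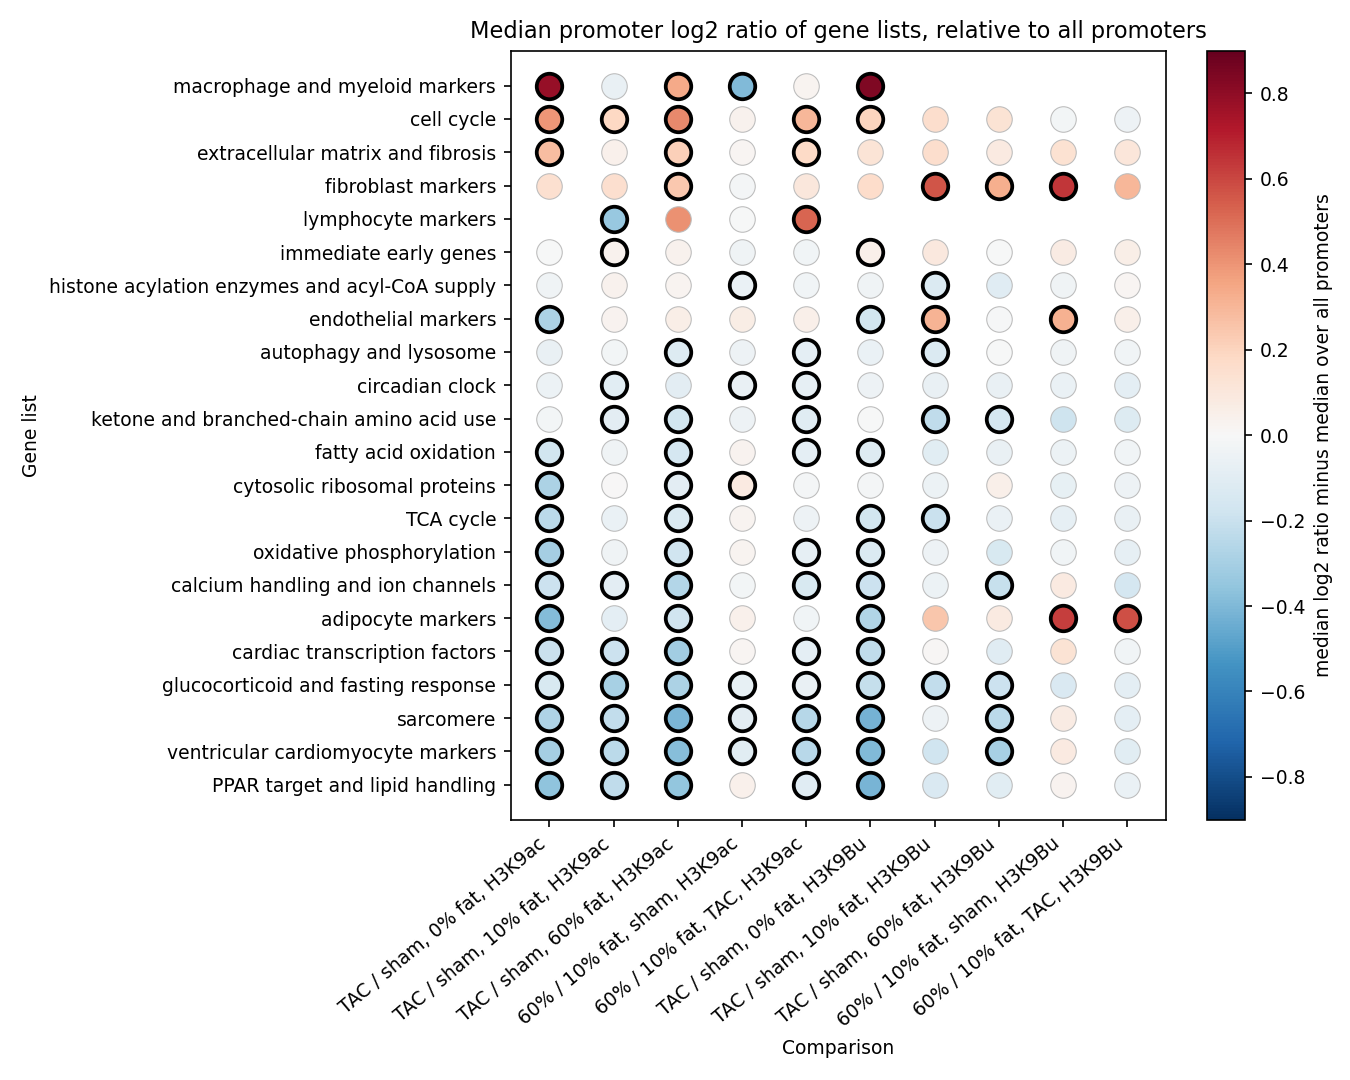
Median log2 ratio of promoter signal of gene lists (vertical axis) in the 10 comparisons within a mark (horizontal axis), relative to the median over all promoters, in colour (red higher, blue lower); black rims mark lists in the lowest or highest 2.5% of random lists, and empty cells have under 4 measured members. The PPAR target list stands at -0.37, -0.23 and -0.36 in H3K9ac after TAC at 0, 10 and 60% fat and the cell cycle list at 0.40, 0.19 and 0.43, the first of which was not apart on peak signal.

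The H3K9ac promoters that differed after TAC overlapped between diets in libraries that share no sample. Of 13453 genes measured at the 3 diets, 28 (in 22 distinct regions) were at least 1.5-fold higher relative to the median at each diet, where independent ratios would give 0.0621, and 12 (in 11 regions) were lower, where 0.0221 would be given. The higher set, named after its values were seen, holds Nppb, Mki67, the mitotic gene Aspm (1.21, 0.62 and 1.21 at 0, 10 and 60% fat), the cell cycle transcription factor gene E2f8 (0.91, 0.89 and 1.19), the load-responsive muscle gene Ankrd1 (0.59, 0.60 and 0.68), the cytokine gene Tnf (0.63, 0.61 and 0.95), and the matricellular gene Wisp1 (1.30, 0.87 and 0.98). Adam12, a metalloproteinase (0.94, 0.62 and 0.68), and Ltbp2, a matrix protein that shares its region with D030025P21Rik (0.69, 0.67 and 0.67), were in it too. For Ltbp2 the mean over all of the gene's regions was -0.16 at 0% and -0.044 at 60% fat. The lower set holds Ucp3. Between 0 and 60% fat, 148 higher and 56 lower genes were shared, against 11.8 and 5.3 if independent; differences between diets were not tested. Genes that share a region or a pathway are not independent, so the counts under independence are a reference and no test.

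**Figure D4:**
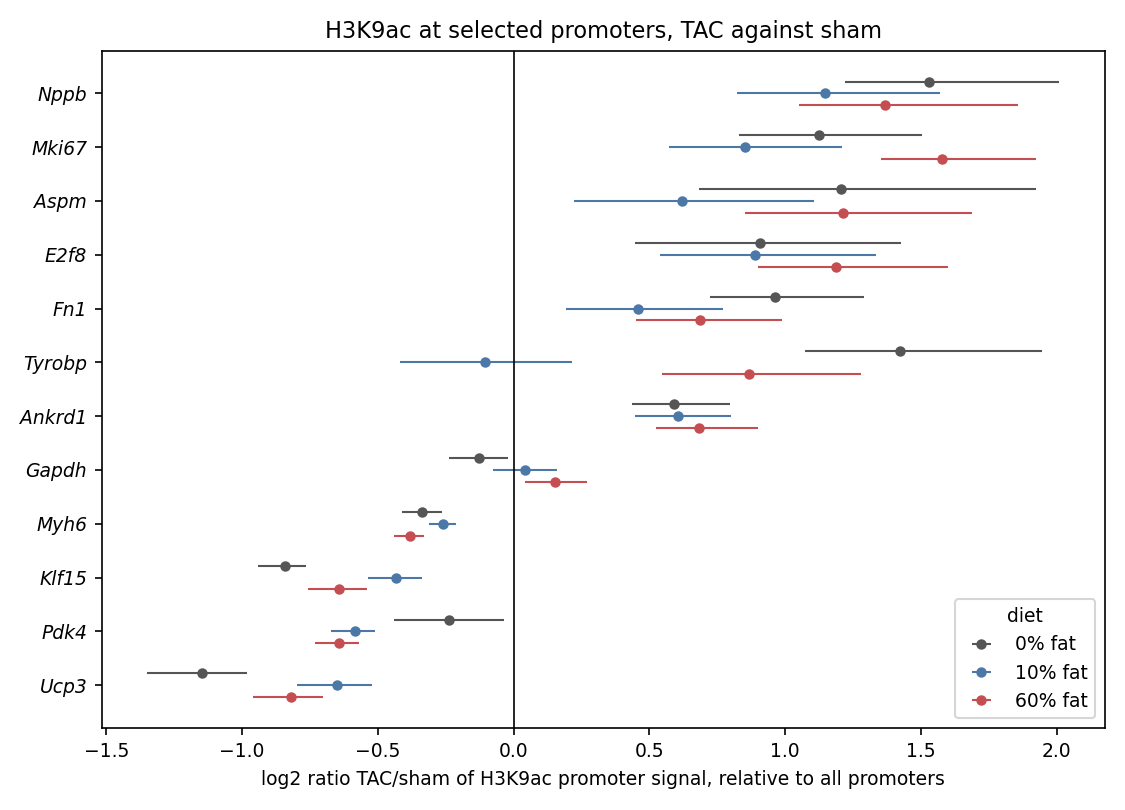
Relative log2 ratio of H3K9ac promoter signal, TAC over sham (horizontal axis), for 12 genes picked after their values were seen, at 0% (grey), 10% (blue) and 60% fat (red); points are single ratios of 1 library each and bars are 95% counting intervals. Nppb lies between 1.15 and 1.53 and Ucp3 between -1.15 and -0.65; Gapdh is below 0 at 0% fat but above 0 as deposited, at 0.12.

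The 60% and 10% fat diets were then compared within each surgery for H3K9ac. In sham hearts, the highest of the ranked promoters was that of Angptl4, an inhibitor of lipoprotein lipase and target of PPAR receptors, at 0.59 (0.48 to 0.71) with signals of 78.8 against 54.4 (chromosome 17, 33778466 to 33782981), and Slc22a5, the carnitine transporter, stood at 0.33 (0.16 to 0.51). Macrophage markers at 60% fat were below 0 in 14 of 14 members (median -0.39, percentile 0), among them Tyrobp at -0.77 (-1.19 to -0.44), the complement gene C1qb at -0.58 (-0.81 to -0.38) and Ptprc at -0.52 (-0.98 to -0.12). The antigen transporter gene Tap1 stood at -0.39 (-0.52 to -0.26) in a region shared with Psmb9, and Kif11 at -0.66 (-0.85 to -0.49). Ribosomal protein genes were above 0 in 16 of 21 members (median 0.08, percentile 100), with Rpl13 at 0.18 and Rpl10a at 0.16.

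Sarcomere genes in sham hearts (median -0.09, percentile 0.04) included Myom2 at -0.57 (-0.98 to -0.21) and Actn2 at -0.31 (-0.48 to -0.16). The fetal and hypertrophy list had a median of -0.16, percentile 0.57. Ventricular markers (median -0.10, percentile 0.42, a call that ended with peak signal), clock genes (median -0.07, percentile 0.88, a call that ended with peak signal), glucocorticoid response genes (median -0.07, percentile 0.58, a call that ended with peak signal), histone acylation enzymes (median -0.06, percentile 1.32, a call that ended with peak signal) and housekeeping genes (median -0.06, percentile 1.39, a call that ended with peak signal) were low by small amounts. Pdk4 at -0.01 (-0.09 to 0.06), Nppb at -0.22 (-0.73 to 0.22) and Mki67 (named here for the TAC comparisons) at 0.14 (-0.22 to 0.50) had intervals that include 0. Of 14007 genes, 27 promoters were at least 1.5-fold higher and 113 lower, around a median of -0.06, and 0 and 9 were 2-fold higher and lower. The split was 44 higher and 76 lower after centring on the median, and 48 higher and 72 lower after lowess centring. The simulation of counting error gave 52 genes, so part of this count is of the size that counting error alone gives. With regions called in both libraries alone, 50 genes passed. Lists were 1 above and 8 below of 31.

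After TAC, Angptl4 was again the highest of the ranked promoters at 60% against 10% fat (0.86 (0.77 to 0.99)), followed by Mki67 (0.86 (0.66 to 1.12)). Cell cycle promoters were above 0 in 17 of 19 members (median 0.30, percentile 100), with Ccnb2 at 0.76 (0.43 to 1.15), Cdk1 at 0.70 (0.51 to 0.93), Uhrf1 at 0.50 (0.32 to 0.69) and the cytokinesis gene Anln at 0.48 (0.31 to 0.66). Matrix genes were above 0 in 18 of 22 (median 0.18, percentile 100), with Thbs1 at 0.74 (0.26 to 1.28), Col1a1 at 0.44 (0.25 to 0.66) and Fn1 at 0.36 (0.13 to 0.62). Lymphocyte markers (median 0.52, percentile 99.76) had 4 measured members, among them Cd79a at 0.89 (0.32 to 1.57) and Cd2 at 0.89 (0.22 to 1.67). The TAC 10% fat library was itself low at this list against the sham 10% fat library (percentile 2.4, a call that did not hold under each alternative). The list was not called apart in TAC against sham at 60% fat, so its ratio here may rest in part on the TAC 10% fat library. Lipogenesis and cholesterol synthesis genes (median 0.09, percentile 98) included the desaturase gene Scd4 at 0.93 (0.21 to 1.82) and Me1 at 0.43 (0.10 to 0.77).

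Sarcomere genes at 60% fat after TAC were below 0 in 17 of 20 members (median -0.26, percentile 0), with Myom2 at -0.86 (-1.31 to -0.48), the myosin light chain gene Myl2 at -0.57 (-0.73 to -0.43) and Tcap at -0.42 (-0.54 to -0.31), and ventricular markers in 13 of 14 (median -0.25, percentile 0). Calcium handling genes (median -0.15, percentile 0) included Kcnip2 at -0.63 (-0.92 to -0.40). PPAR target genes (median -0.11, percentile 0.01) included Plin5 at -0.35 and Vldlr at -0.36, and cardiac transcription factors (median -0.09, percentile 0.37) included Esrrb at -0.75 (-1.11 to -0.43) and the mitochondrial coactivator gene Ppargc1a at -0.28 (-0.41 to -0.17). Mlxipl, a glucose-sensing transcription factor gene, stood at -0.49 (-0.77 to -0.22). Oxidative phosphorylation (median -0.08, percentile 0.27; Cox6a2 -0.50), fatty acid oxidation (median -0.09, percentile 0.16), ketone (median -0.11, percentile 0.05), autophagy (median -0.09, percentile 0.13), clock (median -0.08, percentile 0.66) and glucocorticoid (median -0.07, percentile 1.59, a call that ended with lowess centring and with peak signal) lists were low. Gapdh stood at 0.16.

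Of the genes measured after TAC, 114 promoters were at least 1.5-fold higher and 57 lower at 60% fat, around a median of 0.04, and 3 and 7 were 2-fold higher and lower. The split was 85 higher and 76 lower after centring on the median, and 88 higher and 67 lower after lowess centring. Lists were 4 above and 11 below of 31, and counting error alone gave 66 genes. This comparison shares the TAC 60% fat library with TAC against sham at 60% fat, and the TAC 10% fat library with TAC against sham at 10% fat. Of the genes 1.5-fold higher relative to the median at 60% fat in sham hearts and after TAC, 3 were shared, against 0.267 if independent, and 0 lower genes were shared; 3 were higher in sham hearts and lower after TAC, and 3 the reverse.

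For H3K9Bu, TAC and sham were compared at each diet. At 0% fat, macrophage promoters carried more H3K9Bu after TAC (median 0.84, percentile 100), with 9 of 10 at least 1.5-fold higher: Tyrobp stood at 1.25 (0.80 to 1.93), C1qb at 0.86 (0.65 to 1.19) in a region shared with C1qc, and Sfpi1, the myeloid transcription factor PU.1, at 0.91 (0.65 to 1.28). Nppb stood at 1.75 (1.32 to 2.61), with signals of 19.6 against 5.4. Cell cycle genes (median 0.20, percentile 99.68, a call that ended with lowess centring and with peak signal) included Cdk1 at 1.01 (0.65 to 1.55), Mki67 at 0.86 (0.43 to 1.39) and the mitotic gene Birc5, named for its ratio, at 0.65 (0.43 to 0.90). Inflammation genes (median 0.25, percentile 98.84, a call that ended with peak signal) included Tnf at 0.82 (0.38 to 1.38) and the chemokine gene Ccl2 at 0.99 (0.07 to 2.02). Immediate early genes (median 0.05, percentile 98.49, a call that ended with lowess centring; as deposited -0.01) and stress response genes (median 0.10, percentile 98, a call that ended with peak signal; as deposited 0.03) were higher by small amounts.

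The sarcomere, PPAR and ventricular lists had the lowest H3K9Bu medians after TAC at 0% fat. PPAR target genes were below 0 in 19 of 19 members (median -0.42, percentile 0): Ucp3 stood at -0.91 (-1.16 to -0.72), Cd36 at -0.64 (-0.78 to -0.53) and Pdk4 at -0.52 (-0.80 to -0.26). Sarcomere genes were below 0 in 19 of 20 (median -0.43, percentile 0), with Myh6 at -0.77 (-0.92 to -0.68) in a region shared with D830015G02Rik, Tcap at -0.69 (-0.86 to -0.55) and titin Ttn at -0.61 (-0.80 to -0.46). Ventricular markers (median -0.40, percentile 0) included Pln at -0.75 (-0.91 to -0.65) and the fatty acid binding protein gene Fabp3 at -0.60 (-0.73 to -0.50). Cardiac transcription factors (median -0.23, percentile 0; Esrrb -0.76) and calcium handling genes (median -0.19, percentile 0.04; Kcnh2 -0.75) were low. Hif3a, an oxygen-responsive factor gene, stood at -0.81 (-1.04 to -0.61), Myh7 at -0.67 (-1.36 to -0.05) and Col1a1 at -0.03 (-0.36 to 0.27).

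Endothelial markers were low in H3K9Bu at 0% fat (median -0.17, percentile 0.16, a call that ended with peak signal), with Cldn5 at -0.31 and the growth factor receptor gene Kdr at -0.27. Fatty acid oxidation (median -0.11, percentile 1.13, a call that ended with lowess centring and with peak signal), TCA cycle (median -0.17, percentile 0.01, a call that ended with peak signal), oxidative phosphorylation (median -0.13, percentile 0.16, a call that ended with peak signal), glucocorticoid (median -0.21, percentile 0, a call that ended with peak signal) and adipocyte (median -0.27, percentile 0.04, a call that ended with peak signal) lists were low as well. Of 13666 genes, 240 promoters were at least 1.5-fold higher and 243 lower, around a median of -0.07, and 32 and 18 were 2-fold higher and lower. The split was 324 higher and 167 lower after centring on the median, and 229 higher and 222 lower after lowess centring, so its direction depends on the scaling. Lists were 5 above and 11 below of 29, and counting error alone gave 107 genes. With the H3K9ac ratios of TAC to sham at 0% fat, 174 higher and 50 lower genes were shared, against 14.9 and 5.71 if independent. Between the marks at 10% fat, 13 higher and 0 lower genes were shared, against 1.48 and 0.413, and 5 were lower in H3K9ac and higher in H3K9Bu. At 60% fat 32 and 10 were shared, against 2.48 and 2.13.

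At 10% fat, promoter H3K9Bu was lower in the TAC library than in the sham library at most genes, with a median ratio of -0.99, so a relative value of 0 stands for that ratio as deposited. Genes with a CpG island in their promoter region had a median of -1.02 and those without -0.77. Relative to the median over all genes, fibroblast markers were above 0 in 7 of 7 members (median 0.56, percentile 99.78; as deposited -0.43; percentile 97.81 with lists matched on CpG island), with the homeobox gene Meox1 at 1.69 (1.13 to 2.32) and Pi16 at 0.95 (0.35 to 1.57), or -0.04 as deposited. Endothelial markers (median 0.31, percentile 99.45, a call that ended with lists matched on CpG island; as deposited -0.68) included Sox18 at 0.78 (0.26 to 1.29), the cadherin gene Cdh5 at 0.77 (0.40 to 1.11) and Egfl7 at 0.55 (0.39 to 0.69), which were below 0 as deposited. The highest ranked promoters were weak in the sham library: the mitotic kinase gene Nek2 stood at 3.28 (2.04 to 5.56) with signals of 28.3 against 5, the kinetochore gene Spc24 at 2.85 (1.76 to 4.43) and the transcription factor gene Nfic at 2.83 (2.25 to 3.63).

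Ketone and branched-chain amino acid genes were below the median at 10% fat in 12 of 14 members (median -0.23, percentile 0.12), with Auh at -0.57 (-1.04 to -0.23) and Aldh6a1 at -0.47 (-0.84 to -0.15). TCA cycle (median -0.20, percentile 0.25, a call that ended with peak signal; Ogdh -0.32), glucocorticoid response (median -0.22, percentile 0.12, a call that ended with peak signal; Sesn1 -0.53, Klf9 -0.36), histone acylation (median -0.13, percentile 2.1, a call that ended with peak signal) and autophagy (median -0.13, percentile 2.27, a call that ended with a pseudocount of 5 and with peak signal and with lists matched on CpG island) lists were low. Cnot4 stood at -1.24 (-2.11 to -0.64), Ttn at -0.88 (-1.64 to -0.37), Pdk4 at -0.47 (-0.81 to -0.18) and the carnitine transferase gene Cpt1b at -0.24 (-0.51 to -0.02). Myh6 had an interval that includes 0, 0.03 (-0.57 to 0.51), and so did Gapdh, 0.15 (-0.17 to 0.40), at -0.84 as deposited.

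Of 12046 genes at 10% fat, 236 promoters were at least 1.5-fold higher and 10384 lower in H3K9Bu as deposited (98 and 5894 at 2-fold). The split was 1043 higher and 123 lower after centring on the median, and 920 higher and 230 lower after lowess centring, so its direction depends on the scaling. Lists were 2 above and 5 below of 27, and counting error alone gave 209 genes. This comparison rests on the sham 10% fat library; TAC against sham at 60% fat and 60% against 10% fat after TAC are the H3K9Bu comparisons of this table without it.

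At 60% fat, promoter H3K9Bu was lower after TAC by a median of -0.38. Relative to that, calcium handling genes were low (median -0.21, percentile 0.4), with the calcium release channel gene Ryr2 at -0.88 (-1.89 to -0.15) and Kcnip2 at -0.68 (-1.44 to -0.07). Sarcomere genes (median -0.24, percentile 0.03, a call that ended with peak signal) included Myoz2 at -0.998 (-1.65 to -0.57) and Ldb3 at -0.53 (-0.92 to -0.26), and ventricular markers had a median of -0.30, percentile 0.08, a call that ended with peak signal. Ketone and branched-chain amino acid genes (median -0.16, percentile 1.6) included Mccc1 at -0.57 (-1.13 to -0.17), and glucocorticoid response genes (median -0.19, percentile 0.685, a call that ended with peak signal) included Trim63 at -0.61 (-1.23 to -0.20) and Klf15 at -0.50 (-0.75 to -0.32). Fibroblast markers were high (median 0.33, percentile 98.34, a call that ended with lists matched on CpG island; as deposited -0.06), with Mfap5 at 0.94 (0.15 to 1.86) and Pi16 at 0.70 (0.04 to 1.40).

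The single genes with the highest and lowest H3K9Bu ratios at 60% fat included the mitochondrial import gene Tomm40 at 1.04 (0.36 to 1.83), the centriole kinase gene Plk4 at 0.93 (0.18 to 1.78) and Wiz at -1.58 (-2.85 to -0.67). Pdk4 (-0.40 (-0.91 to 0.05)), Myh6 (-0.06 (-0.80 to 0.61)) and Gapdh (0.28 (-0.05 to 0.61); as deposited -0.10) had intervals that include 0. Of 12046 genes, 30 promoters were at least 1.5-fold higher and 2431 lower (2 and 168 at 2-fold). Only 4567 of these genes had a promoter region called in both libraries, with 0 higher and 446 lower. The median promoter signal of the TAC library, 17.2, lay near the filter's floor of 16.6 for the mean over the 4 libraries. The split was 301 higher and 206 lower after centring on the median, and 305 higher and 187 lower after lowess centring, so its direction depends on the scaling. Lists were 1 above and 5 below of 27, and counting error alone gave 382 genes.

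The 60% and 10% fat diets were compared for H3K9Bu in sham hearts, where the median ratio was -1.07, at -1.11 for genes with a CpG island in their promoter region and -0.78 for those without. Relative to the median over all genes, adipocyte markers were high at 60% fat (median 0.63, percentile 99.74; as deposited -0.44; percentile 98.97 with lists matched on CpG island): the hormone-sensitive lipase gene Lipe stood at 1.56 (1.23 to 1.93), the fatty acid binding protein gene Fabp4 at 1.23 (0.65 to 1.82) and the complement factor gene Cfd at 1.02 (0.26 to 1.78), or -0.04 as deposited. Endothelial markers (median 0.32, percentile 98.87, a call that ended with lists matched on CpG island; as deposited -0.75) included Pecam1 at 0.91 (0.33 to 1.476) and Egfl7 at 0.85 (0.70 to 0.99), both below 0 as deposited. Fibroblast markers (median 0.64, percentile 99.46, a call that ended with peak signal and with lists matched on CpG island; as deposited -0.42) included Meox1 at 1.68 (1.10 to 2.31). Ttc32 stood at 3.43 (2.65 to 4.88) with signals of 33.6 against 5.73, and Nfic and Spc24 at 3.15 (2.59 to 3.94) and 3.20 (2.15 to 4.76), promoters that were weak in the sham 10% fat library shared with the 10% fat TAC comparison.

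Lower promoters at 60% fat in sham hearts included the RNA-binding protein gene Nono at -1.08 (-1.98 to -0.41) and the arginine methyltransferase gene Carm1 at -1.05 (-1.78 to -0.58). Pdk4 stood at -0.53 (-0.90 to -0.24) and Acot1 at -0.54 (-1.27 to 0.00); Gapdh had an interval that includes 0, 0.22 (-0.09 to 0.48), at -0.85 as deposited. Of the genes measured, 363 promoters were at least 1.5-fold higher and 10293 lower (208 and 6968 at 2-fold). The split was 1397 higher and 309 lower after centring on the median, and 1406 higher and 306 lower after lowess centring, so its direction depends on the scaling. Lists were 3 above and 0 below of 27, and counting error alone gave 183 genes.

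After TAC, adipocyte markers were again high in H3K9Bu at 60% against 10% fat (median 0.58, percentile 99.99; as deposited 0.14), in 7 of 7 members. Fabp4 stood at 1.08 (0.46 to 1.72), Lipe at 0.68 (0.30 to 1.08) and Cebpa, an adipocyte transcription factor gene, at 0.62 (0.17 to 1.10); with regions near the gene start alone, Fabp4 was at -0.21. The tubulin gene Tubb5 stood at 1.64 (0.81 to 2.63) and Prx at 1.31 (0.64 to 2.05). The short-chain acyl-CoA dehydrogenase gene Acads, whose enzyme oxidises butyryl-CoA, was low at -0.82 (-1.75 to -0.11), and near the gene start alone at 0.0035. Cox16 stood at -0.99 (-1.66 to -0.49), Pdk4 at -0.48 (-0.99 to -0.05) and Gapdh at 0.33 (0.00 to 0.66), with -0.10 as deposited. Around a median of -0.44, 69 promoters were at least 1.5-fold higher and 3640 lower (3 and 346 at 2-fold). Only 4480 genes had a promoter region called in both libraries, with 0 higher and 761 lower. The split was 578 higher and 308 lower after centring on the median, and 539 higher and 260 lower after lowess centring, so its direction depends on the scaling. Lists were 1 above and 0 below of 27, and counting error alone gave 381 genes. In sham hearts and after TAC, 400 higher genes and 31 lower genes were shared, against 67 and 7.9 if independent. Genes with a CpG island had a lower median ratio in both, after TAC -0.45 against -0.34 without. The part of this in the shared counts was not tested.

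At 0% fat both marks were measured over the same regions, so their promoter signals were compared within each surgery. The marks were read with different antibodies, and a ratio of their signals is not a ratio of the marks. In sham hearts, ribosomal protein promoters had less H3K9Bu for their H3K9ac in 21 of 21 members (median -0.35, percentile 0): Rpl3 stood at -1.34 (-2.10 to -0.79), Rpl27 at -0.88 (-1.07 to -0.75) and Rps2 at -0.72 (-0.84 to -0.64), the first and last in regions shared with other genes. Macrophage markers (median -0.30, percentile 0.19; C1qb -0.63) and fibroblast markers (median -0.32, percentile 0.22, a call that ended with peak signal) were low. Lipogenesis genes leaned to H3K9Bu (median 0.23, percentile 98.21; as deposited -0.38), with Scd4 at 1.20 (0.57 to 1.89), the fatty acid synthase gene Fasn at 1.07 (0.59 to 1.53) and the sterol regulator gene Srebf1 at 0.88 (0.61 to 1.17), which was at -0.27 with regions near the gene start alone.

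Ranked promoters leaning to H3K9Bu in sham hearts included Ky, a muscle gene, at 3.56 (2.81 to 4.77) (chromosome 9, 102504902 to 102505281), the glutamate transporter gene Slc1a7 at 2.54 (2.07 to 3.21) and the lipocalin gene Apod at 2.06 (1.67 to 2.55). Myh7 stood at 1.30 (0.69 to 1.99), Myh6 at -0.35 (-0.45 to -0.28) and Nppb at -0.61 (-1.46 to -0.11), and Gapdh had an interval that includes 0, 0.07 (-0.07 to 0.18), at -0.54 as deposited. Around a median of -0.61, 339 promoters were at least 1.5-fold higher and 7203 lower in H3K9Bu (150 and 1327 at 2-fold), with 1348 higher and 394 lower after centring on the median, and 1236 higher and 435 lower after lowess centring, so its direction depends on the scaling. Lists were 1 above and 3 below of 29, and counting error alone gave 79 genes.

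After TAC at 0% fat, macrophage markers had less H3K9Bu for their H3K9ac (median -0.37, percentile 0), with C1qa at -0.57 (-0.85 to -0.39) and C1qb at -0.52 (-0.75 to -0.38). Sarcomere genes (median -0.14, percentile 1.12, a call that ended with peak signal) included Myh6 at -0.80 (-0.95 to -0.73), which was at 0.48 with regions near the gene start alone, and Ttn at -0.61 (-0.80 to -0.49). Ventricular markers (median -0.14, percentile 2.21, a call that ended with a pseudocount of 5) included Pln at -0.70 (-0.87 to -0.63), which was at 0.59 as the mean over all of its regions. Lmod2, a thin filament gene, stood at -0.82 (-1.003 to -0.71). Matrix genes (median -0.16, percentile 0.11, a call that ended with peak signal; Col1a2 -0.65), cell cycle genes (median -0.13, percentile 1.58, a call that ended with peak signal and with lists matched on CpG island), ribosomal protein genes (median -0.15, percentile 0.27, a call that ended with peak signal), fibroblast markers (median -0.22, percentile 0.28, a call that ended with peak signal) and endothelial markers (median -0.14, percentile 2.07, a call that ended with a pseudocount of 5 and with peak signal) were low.

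Genes leaning to H3K9Bu after TAC included Scgb3a1 at 3.27 (2.55 to 4.46), the ceruloplasmin gene Cp at 1.60 (1.28 to 1.98), the adenylate kinase gene Ak1 at 1.38 (1.02 to 1.76) and the Z-disc gene Myoz1 at 1.32 (0.98 to 1.70). Nppb stood at -0.40 (-0.79 to -0.10) and Gapdh at 0.19 (0.05 to 0.30), with -0.73 as deposited. Around a median of -0.92, 155 promoters were at least 1.5-fold higher and 11846 lower in H3K9Bu (49 and 4838 at 2-fold). The split was 839 higher and 65 lower after centring on the median, and 809 higher and 81 lower after lowess centring, so its direction depends on the scaling. Lists were 0 above and 8 below of 29, and counting error alone gave 73 genes.

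The regions of both marks overlapped to different extents. At 0% fat, 55.1% of H3K9Bu regions in sham hearts and 69.4% after TAC were also H3K9ac regions, as merged by the authors. At 10% fat the shares were 72.5 and 73.6%, and at 60% fat 55 and 53.8%, by an overlap of at least 1 bp. The share of H3K9ac regions with H3K9Bu was 80.5% in sham and 45% in TAC hearts at 10% fat, 47.4 and 23.5% at 60% fat, and 66.3 and 78.4% at 0% fat. The H3K9Bu libraries at 10 and 60% fat held 41348, 19628, 29473 and 14679 called regions in the same order, and a shorter list limits this share. An overlap of 50% of each region gave 13.9 to 48.3% over both marks at 10 and 60% fat.

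Across genes, the H3K9ac ratios of TAC to sham were correlated between diets (Pearson r 0.53 between 0 and 60%, 0.49 between 10 and 60% and 0.29 between 0 and 10% fat; Spearman rho 0.48, 0.44 and 0.24). The H3K9Bu ratios were correlated at r 0.26, 0.25 and 0.16 for the same pairs. Between marks, r was 0.43 at 0%, 0.28 at 60% and 0.14 at 10% fat. The diet ratios of H3K9ac were nearly unrelated between sham and TAC hearts (r 0.04), while those of H3K9Bu had r 0.55. Both H3K9Bu diet ratios had lower medians for genes with a CpG island, -1.11 against -0.78 without in sham and -0.45 against -0.34 after TAC. Whether this shared difference gives that r was not tested. Between marks, r of the diet ratios was 0.19 in sham and 0.14 in TAC hearts. These 13 correlations are across genes, which are not independent replicates, and no pair shares a library.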

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

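The tests on library depth, on enrichment over background, on the sham 60% fat library, on lowess scaling and on a larger share of non-myocytes were chosen only after the result was seen. The test on spread of signal was set before. Bootstrap intervals resample regions, genes or list members within a pair of libraries, so they leave out variation between libraries.

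The endothelial marker list lay on opposite sides of the random lists in H3K9Bu after TAC, at a relative median of -0.171 (percentile 0.16) at 0% fat and 0.314 (percentile 99.45) at 10% fat, a difference of -0.485 that was not tested; the former call ended on peak signal, and the latter rests on the sham 10% fat library and ended with random lists matched on CpG island.

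Promoter H3K9Bu was lower in the TAC 10%, sham 60% and TAC 60% fat libraries than in the sham 10% fat library. Depth alone would lower all regions by 1 factor, but among regions called in all 4 libraries the median log2 ratio of sham 60% to sham 10% fat was -1.01 with a CpG island (3653 regions) and -0.26 without (3062 regions), a difference of -0.75 (95% bootstrap interval -0.77 to -0.72). Weaker enrichment over background in the 3 libraries is a candidate explanation that the values allow: of 1704 regions called in the 3 and not in sham 10% fat, 28.7% (26.6 to 30.9) were also called in the separate 0% fat sham H3K9Bu library, against 68.7% of the 21352 called in sham 10% fat alone. Part of this gap may follow from the selection, since the former regions were picked for absence from a sham H3K9Bu library and the latter for presence. The sets also differ in kind, with a CpG island in 2.0 and 20.9% and a promoter in 26.1 and 35.8%. The gap thus does not tell weaker enrichment from a real change of the mark. A biological effect of TAC and of 60% fat on this mark stays open and was not tested. TAC against sham at 60% fat leaves out the sham 10% fat library and had a median of -0.38 over genes. There the same regions stood at -0.33 with a CpG island and -0.29 without, a difference of -0.0385 (-0.05 to -0.03). Depth alone is a candidate explanation if so small a difference is allowed, though its interval leaves out 0. In 60% against 10% fat after TAC, also without that library, regions with and without an island stood at -0.36 and -0.13, which 1 factor would not give.

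Cell cycle promoters carried more H3K9ac after TAC at 60% fat. A low sham 60% fat library as the sole cause is argued against, since the list stood at percentile 100 in 60% against 10% fat after TAC. That comparison does not use it but shares the TAC 60% fat library, so it does not show whether the sham 60% fat library was low. The list was not called apart between the sham 60 and 10% fat libraries, though Kif11 was low there. Scaling that depends on signal is argued against as well, since the list's median was 0.39 after lowess centring (95% bootstrap interval 0.22 to 0.63) and 0.43 before it. Whether all non-myocyte types hold a larger share could not be decided. It would raise the markers of each type alike. Macrophage and endothelial marker medians differed by 0.28 (95% bootstrap interval 0.06 to 0.52) in TAC against sham. But macrophage markers were lower in the sham 60% than in the sham 10% fat library, and were not apart between TAC and sham at 10% fat. The difference of 0.28 thus rests largely on the sham 60% fat library. In 60% against 10% fat after TAC, which uses neither sham library, macrophage and endothelial medians differed by -0.030 (-0.12 to 0.11). As deposited they stood at 0.07 and 0.10, against a median of 0.04 over all promoters, and neither list was called apart. The cell cycle list stood at 0.34 as deposited. A difference near 0 between lists that were not apart shows no shared rise, so it does not decide the question. More cycling cells, of a type that is more numerous or of any type, is a hypothesis that stays open, as does a peculiarity of the 1 TAC 60% fat library.

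H3K9ac was higher at most promoters after TAC at 0% fat. Depth alone, which would shift all regions by 1 factor, is argued against. Among regions called in all 4 libraries, those with a CpG island were higher by 0.23 (10176 regions) and those without by 0.10 (5578 regions). That difference of 0.13 (95% bootstrap interval 0.11 to 0.14) goes against a common factor. Over the genes' strongest promoter regions the order turned, with medians of 0.24 with an island (11029 genes) and 0.32 without (2637 genes). A common factor would not give this either, but which kind of region rose more depends on the regions taken. A wider spread of signal around promoters in the sham 0% fat library may account for the shift: over 7399 genes, the strongest promoter region exceeded the gene's other promoter regions in the log2 ratio by a median of 0.52 (0.50 to 0.54), against 0.03 and 0.13 at 10 and 60% fat. The other promoter regions include some called in the sham H3K9ac library alone (7007 regions in all, against 2542 in the TAC H3K9ac library alone). Their low ratios follow from that selection, so the value of 0.52 in part restates those calls. A response to TAC on the 0% fat diet stays open and was not tested, and the list percentiles at this diet rest on the same sham library.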

How the results depend on the processing

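The alternatives of regions near the gene start and of random lists matched on CpG island were chosen after seeing the data, the others before; their causes were not tested except where named. No paired analysis was possible within a diet because each group has 1 library, and TAC and sham were not paired across diets. Counts are genes at least 1.5-fold apart. Centring moves each count by construction, since it takes away the median. Centred on the median, TAC against sham in H3K9ac gave 1097 genes at 0% and 545 at 60% fat, and the larger side turned from lower to higher in H3K9Bu for TAC against sham at 0% (491), 10% (1166) and 60% fat (507), for 60% against 10% fat in sham (1706) and TAC hearts (886), and for H3K9Bu against H3K9ac in sham (1742) and TAC hearts (904). After lowess centring the same 7 comparisons turned, with 451, 1150, 492, 1712, 799, 1671 and 890 genes in that order. H3K9ac after TAC turned to the lower side at 0% (958) and 10% fat (176) and gave 525 genes at 60% fat. On peak signal, H3K9ac after TAC gave 3460 genes at 0% and 310 at 10% fat, 60% against 10% fat in sham H3K9ac gave 235, and H3K9Bu against H3K9ac in sham hearts gave 4287; the cause was not tested.

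With a pseudocount of 5 there were fewer genes by construction: 98 in H3K9ac after TAC at 10% fat, 76 and 101 in H3K9ac for 60% against 10% fat in sham and TAC hearts, 296 and 1193 in H3K9Bu after TAC at 0 and 60% fat, and 2121 in H3K9Bu for 60% against 10% fat after TAC. Without the filter, more genes count: 341, 316 and 314 for the first 3 of these, and 775 in H3K9Bu after TAC at 0% fat, where the larger side turned to higher. Regions called in both libraries gave 96, 50 and 108 for the first 3, and in H3K9Bu 149 and 446 after TAC at 0 and 60% fat and 761 for 60% against 10% fat after TAC, as fewer genes remain. The mean over all regions of the gene gave 84 and 96 for 60% against 10% fat in sham and TAC H3K9ac and 2058 in TAC H3K9Bu. Near the gene start, H3K9Bu after TAC at 0% fat had 437 genes, the larger side higher. The cause was not tested for the latter settings.

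Single genes turned as the mean over all regions, Ltbp2 in H3K9ac after TAC (-0.16 at 0% and -0.044 at 60% fat) and Pln in H3K9Bu against H3K9ac after TAC (0.59), and near the gene start, Fabp4 (-0.21) and Acads (0.0035) in H3K9Bu for 60% against 10% fat after TAC, Srebf1 (-0.27) in sham and Myh6 (0.48) in TAC hearts for H3K9Bu against H3K9ac; another region stands for the gene there. Of 1686 alternative values of single genes, 1494 stayed within their counting interval, 185 left it and 7 turned. Without the filter and with regions called in both libraries, the gene's own ratio stays and only the median moves. The 254 of 254 and 182 of 182 values that stayed there thus say little. As the mean over all regions, 145 of 254 stayed, 106 left the interval and 3 turned, and on peak signal 193 of 254 stayed and 61 left it. A turn was counted only for genes at least 1.5-fold from the median in the main setting. Smaller ratios that changed sign are not among the 7.

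Overlaps depend on the rule. With 50% of each region shared, H3K9Bu regions in H3K9ac came to 33.2 and 39.4% (sham, TAC) at 10% and 27.7 and 27.6% at 60% fat, and H3K9ac regions in H3K9Bu to 48.3 and 28.3% and to 28.8 and 13.9%. With regions at or above the table's median signal, the former came to 52.2 and 67.6% at 0%, 62.5 and 65.5% at 10% and 44.9 and 38.8% at 60% fat, and the latter to 60.3 and 69.5% at 0%, 91.2% in sham hearts at 10% and 17.5% in TAC hearts at 60% fat; the cause was not tested. The 39 alternative correlations moved by less than 0.1. Of 113 list calls, 63 held under lowess centring, peak signal, a pseudocount of 5 and matching on CpG island. Peak signal ended 43 calls and added 20, lowess centring ended 6 and added 4, the pseudocount ended 5 and added 4, and matching on CpG island ended 7 and added 7; no list changed sides. Few estimated tags in the merged regions limit the H3K9Bu libraries at 10 and 60% fat most, with 183 to 382 unchanged genes past 1.5-fold by counting error. Whether depth or enrichment made these tags few is unknown, since total reads are.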

Other observations

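The regions away from promoters were named after their values were seen, and the test on sarcomere genes was set before its result.

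Away from promoters, regions within Zbtb16, a transcription factor gene induced by glucocorticoids, were among the lowest ranked for H3K9ac after TAC at each diet. They were different regions at each diet, and the gene's other regions were not counted. The lowest of them stood at -1.67 (-2.01 to -1.43) at 0% fat (chromosome 9, 48725271 to 48726664), -0.55 (-0.72 to -0.41) at 10% fat (chromosome 9, 48727393 to 48730548) and -0.86 (-1.10 to -0.65) at 60% fat, relative to the median over regions away from promoters. At 10% fat the calcium channel subunit gene Cacnb2 had a region at -0.96 (-1.20 to -0.77), and at 60% fat Acsl1, which activates fatty acids, had one at -0.81 (-0.98 to -0.68). At 0% fat regions of the blood cell transcription factor gene Runx1 and of Ncoa7 were higher, at 1.24 (1.07 to 1.496) and 1.76 (1.15 to 2.59). In H3K9Bu at 0% fat, regions of the myoglobin gene Mb and of Prkd1 were lower after TAC, at -1.06 (-1.70 to -0.53) and -1.11 (-1.59 to -0.72), and a region of Rac2, a GTPase of blood cells, was higher at 1.06 (0.60 to 1.56). A region of Mb also had less H3K9ac at 60% than at 10% fat after TAC, at -0.57 (-0.69 to -0.47).

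At 0% fat, 4025 regions away from promoters were called for H3K9Bu in sham and TAC hearts and for H3K9ac in neither. Their median length was 477 bp, 0.124% held a CpG island, and their median signals were 34.4 and 28.9 in H3K9Bu (sham and TAC) against 14.7 and 15.8 in H3K9ac. The genes with the most of them, named after the counts were seen, were Arhgap26 (12 of its 56 regions away from promoters), Ninj2 (10 of 21), the sarcomere assembly gene Fhod3 (10 of 24), Tacc2 (10 of 30), Stk10 (9 of 21), Prkce (9 of 33) and Nfia (9 of 57). A hypothesis that these regions gather at sarcomere genes was tested against random lists matched on the number of regions per gene. Of 16 sarcomere genes 37.5% had one, against a random median of 43.8%, at percentile 31.5. The test thus gave the hypothesis no support. A value within the random spread of so few genes cannot exclude a small gathering.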
